A study of Homo sapiens with 8 samples.

How the data were processed

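Poly(A)-selected messenger RNA was sequenced from 8 libraries of human HEK293T cells, a line derived from embryonic kidney that here carries a TRE3G-GFP reporter, a green fluorescent protein gene behind a promoter with tet operator sites. Per the labels, the cells were grown in medium with 10% fetal bovine serum, were transfected with plasmids for an activator protein and for a guide RNA, and were sorted on mCherry and BFP fluorescence 2 days later. RNA was fragmented and copied with random hexamers, and libraries were read on an Illumina NovaSeq instrument. The labels name 4 groups of 2 libraries each. dCasMINI-VPR, a small Cas protein without cutting activity joined to the VP64-p65-Rta activation domains, was paired with a non-targeting guide (sgNT) or a guide named Tet (sgTet). dCas12a-VPR, a larger Cas protein joined to the same domains, was paired with a non-targeting (crNT) or a Tet guide (crTet). The guide sequences are not given in the labels, which also do not state whether the replicates came from separate transfections, or any batch, date or pairing.

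The authors aligned reads to hg38 with STAR (version not given in the sources used here) and deposited raw counts of reads per gene, one file per library, with no normalization. Each deposited file holds 60652 gene rows, 3 count columns and 4 totals that name no gene (unmapped, multimapping, no feature and ambiguous). The first count column ignores strand and was used here, since the other 2 split the gene reads about evenly. An added EGFP row counts reads of the reporter. The 4 totals were left out of library sizes and tests. Symbols were found for 42024 gene rows, and positions for 58361 from the GENCODE release 29 annotation of hg38. No read-level data were used here, and no genome sequence was searched for guide sites.

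Counts were fitted with edgeR 4.0.16 (quasi-likelihood, robust) in R 4.3.3, in 1 model of all 8 libraries with a mean for each of the 4 groups, TMM factors and a filter on low counts by group. This tested 16606 genes. The common biological coefficient of variation was 8.04%, with 4 residual degrees of freedom per gene and 28.9 prior degrees of freedom. A replicate left alone in its group when another is left out is therefore assumed to vary like the other groups. The 5 contrasts were the guide effect with dCasMINI-VPR (sgTet minus sgNT), the guide effect with dCas12a-VPR (crTet minus crNT), the difference between these effects, their mean, and the construct difference over both guides (dCasMINI-VPR minus dCas12a-VPR). The edgeR and camera tests were two-sided, and Fisher's exact tests of overlap and the permutation test of neighbouring genes were one-sided. Genes were called at a Benjamini-Hochberg adjusted p of 0.05 over all genes tested in the contrast. CPM are counts scaled to the TMM-adjusted library size, given as mean ± SD over the 2 libraries of a group. Log2 fold changes are given ± SE, where SE is the size of the fold change divided by the square root of F. The log2 CPM by which libraries were compared for overlap used a prior count of 2. Fitted fold changes of a gene without reads in a group rest on the small default prior count of edgeR. For such a gene the fold is given instead as a lower bound, against a floor of 3 counts over the group's 2 libraries.

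Before the data were examined, 22 gene lists were fixed with 586 genes, of which 585 were matched (SOD2 was not): interferon response, NF-kB targets, immediate early genes, p53 targets, unfolded protein response, ATF4 response, heat shock response, cholesterol synthesis, hypoxia and glycolysis, S phase, G2 and M phase, replication-dependent histones, cytosolic ribosomal proteins, mitochondrially encoded mRNAs, nuclear oxidative phosphorylation genes, metallothioneins, CRISPR activation benchmark genes, and neuronal, haematopoietic, fibroblast, endothelial and epithelial markers. Lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the lists within a contrast. Camera was repeated with an estimated correlation, and fry was run as a self-contained test. Counts of called members are given over all genes tested and adjusted over the list alone. The groups, contrasts, tests, thresholds, rule for named genes and most alternatives were also chosen before the data were examined.

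Named genes were taken by a fixed rule. In each contrast these were the 12 called genes with the largest rise and the 12 with the largest fall, or 6 and 6 for the difference and the mean, among genes with a symbol and a mean log2 CPM of at least 1 whose libraries did not overlap between the 2 sides. No such separation was asked for the difference. Up to 4 called members of each list, by smallest adjusted p, were added, and RELA, GAPDH, ACTB and EGFP were reported whatever their values. NEUROG3, TNNT3, C4B, C4A, F10, UPK1B, IL18, B3GALT5 and LINC02798 fell outside the rule and were chosen after their values were seen, as were the genes that complete a small count of a list.

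The alternatives were DESeq2 1.42.0, RLE factors, library size alone, no filter, a filter of CPM of at least 1 in 2 libraries, glmTreat against a fold change of 1.5, the forward and reverse strand columns, each library left out in turn, replicate number as a block over all groups or within each construct, removal of mitochondrially encoded genes, and only the libraries of 1 construct or 1 guide. An alternative with per-library offsets for a smooth trend on exon length and GC content (mgcv 1.9.3), camera on values corrected in the same way, and camera without each library were added after the data were seen. Replicate numbers did not pair the libraries across all groups. Across genes, the log2 ratio of replicate 2 to replicate 1 correlated between groups with r from -0.135 to 0.287. The highest r was between sgTet and crTet, so a difference shared by their libraries of the same number remains open. No block was used in the reported fits. Tables and figures were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.

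The fit was tested on simulated data in which 50 genes per fold, each with a mean CPM of at least 1, were changed. With dCasMINI-VPR it recovered 86%, 84% and 100% of genes changed 1.5-fold, 2-fold and 4-fold, and with dCas12a-VPR 56%, 84% and 96%. Between 6.64% and 7.62% of the calls fell on unchanged genes. The p53 targets were also raised, by a log2 fold change of 0.6. The recovery rates do not cover genes of lower expression. The simulated libraries of a gene all had the same spread. In the data replicates differed more in sgTet (chi-square per degree of freedom 13.8) than in sgNT, crNT and crTet (3.94, 3.19 and 6.92). The simulation therefore gives no error rate for groups of unequal spread. In a simulation with no changed gene but a transcript length trend in sgTet, 319 genes were called without the correction and 5 with it. The reported fits are therefore open to such trends. No GC trend was simulated, so its removal was not tested.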

Results

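Gene expression was measured in 8 libraries of sorted HEK293T reporter cells, 2 for each of dCasMINI-VPR sgNT, dCasMINI-VPR sgTet, dCas12a-VPR crNT and dCas12a-VPR crTet. Reads counted in genes came to 19433237 and 17474404 in the sgNT libraries, 20443073 and 21081942 in sgTet, 19142986 and 20061468 in crNT, and 20362381 and 19709269 in crTet. At that depth 3 reads correspond to between 0.142 and 0.172 CPM in a library, and this floor covers counting error alone, since the reads carry no molecular identifiers. Between 22365 and 23792 genes had a read in a library. Unmapped reads made up 14.4% and 12.7% of the crNT libraries and between 8.32% and 9.62% of the other 6. Mitochondrially encoded genes held 2.59% and 2.77% of gene reads in sgNT, 3.96% and 2.96% in sgTet, 2.41% and 2.47% in crNT, and 3.26% and 3.33% in crTet.

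The Tet guides raised the reporter transcript with either activator. EGFP, the reporter gene added to the reference by the authors, went from 3.83 ± 0.846 CPM in sgNT to 1007 ± 123 CPM in sgTet, which is a 263-fold rise (log2 fold change 8.05 ± 0.13, adjusted p = 3.26e-26). With dCas12a-VPR it went from 2.71 ± 0.076 CPM in crNT to 756 ± 68.2 CPM in crTet, a 279-fold rise (8.12 ± 0.13, adjusted p = 5.18e-26). In sgTet it ranked 100 among the 16606 genes tested by mean CPM, and in crTet 141. The guide effects on EGFP did not pass the test of their difference (-0.07 ± 0.21, adjusted p = 0.904). Over both guides EGFP was higher with dCasMINI-VPR (0.45 ± 0.10, adjusted p = 0.0054), a call lost without sgNT replicate 2 or with forward-strand counts (adjusted p = 0.106). With a replicate block within construct, which compared the replicate 1 levels of the constructs alone, EGFP was not called either (0.245). RELA, which encodes the NF-kB subunit p65, did not pass the guide test of either activator (0.08, adjusted p = 0.753 with dCasMINI-VPR, and -0.03, adjusted p = 0.877 with dCas12a-VPR). Neither did the glycolytic enzyme GAPDH (0.02, adjusted p = 0.948, and 0.10, adjusted p = 0.442) or the actin gene ACTB (0.19, adjusted p = 0.173, and 0.16, adjusted p = 0.136). For ACTB the mean guide effect over both activators did pass (0.18, adjusted p = 0.0185), a call lost without sgNT replicate 1 or 2 (adjusted p = 0.12 and 0.136) or crNT replicate 1 or 2 (0.201 and 0.0842). ACTB was higher with dCasMINI-VPR over both guides (0.19, adjusted p = 0.0054), a call lost without sgNT replicate 1 (adjusted p = 0.0613) or crNT replicate 1 (adjusted p = 0.0704).

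**Figure D1:**
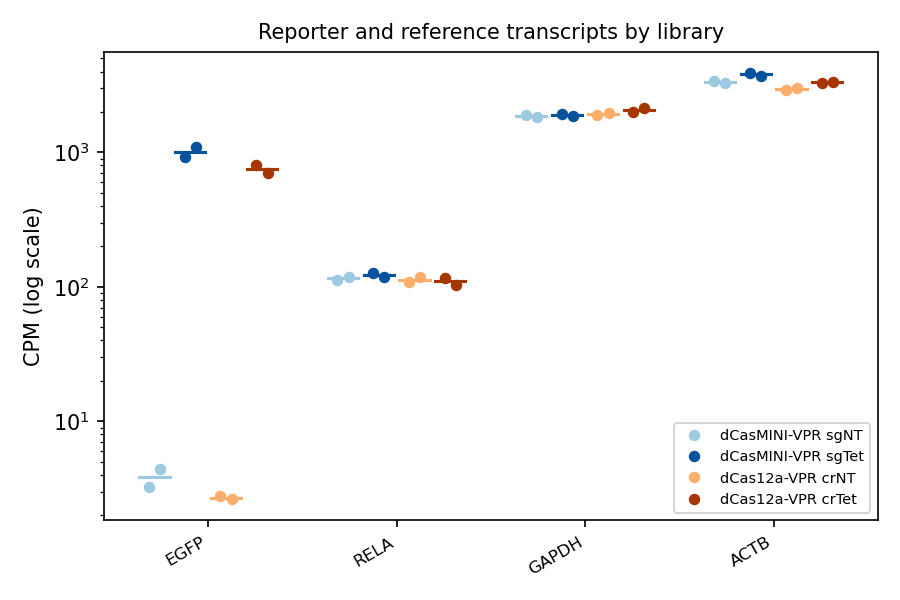
CPM (log axis) of EGFP, RELA, GAPDH and ACTB in each of the 4 groups; points are libraries and bars are group means. EGFP lies at 3.83 and 2.71 CPM with the non-targeting guides and at 1007 and 756 CPM with the Tet guides.

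Which other genes the Tet guide changed with dCasMINI-VPR was asked by comparing sgTet with sgNT. NKX2-5, a homeobox transcription factor of heart development (ENSG00000183072.10, hg38 chromosome 5, 173232109 to 173235357), rose 3.88-fold, from 88.2 ± 1.29 to 343 ± 2.86 CPM (1.96 ± 0.08, adjusted p = 1.12e-18). VGLL2, a transcriptional cofactor of skeletal muscle (ENSG00000170162.14, chromosome 6, 117265558 to 117273565), rose 7.15-fold, from 2.75 ± 0.198 to 19.7 ± 2.2 CPM (2.84 ± 0.22, adjusted p = 2.02e-10). GDPD3, a lysophospholipase D gene (ENSG00000102886.15, chromosome 16, 30104810 to 30113856), rose 8.31-fold, from 0.714 ± 0.367 to 6.04 ± 0.834 CPM (3.05 ± 0.41, adjusted p = 1.88e-05). LIMS2, an adaptor of integrin adhesions, rose 3.83-fold from 1.91 CPM (adjusted p = 1.23e-04), and RBM47, an RNA-binding protein gene, by 0.97 (adjusted p = 9.19e-05). The stress-responsive transcription factor ATF3 rose 1.81-fold, from 175 ± 13.0 to 317 ± 19.9 CPM (0.86 ± 0.08, adjusted p = 5.37e-09). Among the genes that fell were IRS4-AS1, an antisense RNA of the IRS4 locus (-1.67 ± 0.14, adjusted p = 4.96e-10), the homeobox gene HOXA7 (-1.45 ± 0.20, adjusted p = 4.43e-05) and BST2, which encodes tetherin, an interferon-induced membrane protein (-0.74 ± 0.10, adjusted p = 1.38e-05). All 9 genes were called whichever of the 8 libraries was left out, but HOXA7 lost its call with forward-strand (adjusted p = 0.164) or reverse-strand counts (0.0928). IRS4-AS1 and HOXA7 stood apart in sgNT, at 51.5 and 16.8 CPM, against 16.2 and 6.12 in sgTet and 13.5 and 6.80 in crTet. Compared after the result was seen, their log2 levels in sgNT were also above those in crNT, by 2.10 and 1.75. For these genes a high level in sgNT cannot be told apart from a fall with the Tet guide.

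In all, 78 genes rose and 54 fell with dCasMINI-VPR, and 36 of the 78 rose by at least 2-fold. Without sgTet replicate 2 the count was 1475 and without sgTet replicate 1 it was 88, with 66 of the 132 among them, so it depended on which sgTet library was kept. Without sgNT replicate 1 it was 51, and without sgNT replicate 2 it was 50. The sgTet libraries differed more from each other than those of other groups (chi-square per degree of freedom 13.8, against 3.94, 3.19 and 6.92 in sgNT, crNT and crTet). Scaling by library size alone gave 68 higher and 80 lower. Removing the length and GC trend gave 141 and 75, with 119 of the 132 among them.

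The genes with the larger rises were for the most part almost silent in sgNT. Leaving out EGFP, 29 genes were at least 4-fold higher in sgTet, of which 14 are protein coding, 11 are annotated as other gene types and 4 are not in the annotation. In sgNT 28 of the 29 lay below 1 CPM, and 8 had no read. Their median rose from 0.185 CPM in sgNT to 3.50 CPM in sgTet, while the medians in crNT and crTet were 0.150 and 0.202 CPM. Chosen after their values were seen, NEUROG3, which encodes a transcription factor of endocrine pancreas development (ENSG00000122859.5, chromosome 10, 69571698 to 69573238), had no read in sgNT and 266 reads in sgTet, 6.53 ± 0.962 CPM, at least 80.3-fold higher (adjusted p = 1.18e-08). TNNT3, the fast skeletal muscle troponin T gene (ENSG00000130595.19, chromosome 11, 1919562 to 1938706), had no read in sgNT and 217 reads in sgTet, 5.32 ± 1.16 CPM, at least 65.5-fold higher (adjusted p = 1.34e-06). C4B, a complement component, went from 0.136 to 3.86 CPM (adjusted p = 2.32e-05), and F10, coagulation factor X, from 0.210 to 3.96 CPM (adjusted p = 6.26e-05). UPK1B, a uroplakin of bladder epithelium, went from 0.290 to 3.84 CPM (adjusted p = 1.31e-04), and B3GALT5, a galactosyltransferase, from 0.645 to 4.04 CPM (adjusted p = 0.00118). These 6 genes were called whichever library was left out, but TNNT3 lost its call with DESeq2 (adjusted p = 0.132). Counts that ignore strand cannot separate B3GALT5 and F10 from genes that overlap them, and C4B has a near-identical paralog, C4A. Of the 29 genes, 15 were called without sgNT replicate 1 and 17 without sgNT replicate 2.

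**Figure D2:**
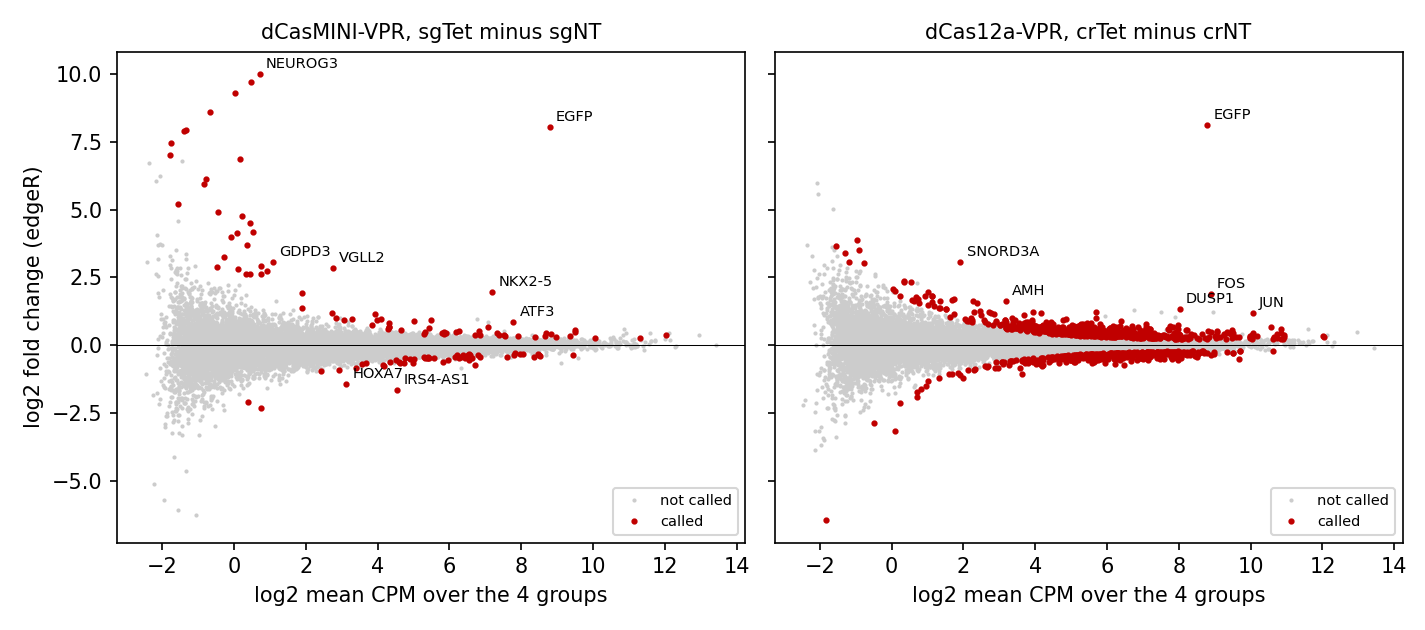
Log2 fold change with the Tet guide against log2 mean CPM over the 4 groups for the 16606 genes tested, with dCasMINI-VPR in one panel and dCas12a-VPR in the other; called genes are red and others grey, and fitted values of genes without reads in a group depend on the prior count. With dCasMINI-VPR 78 genes rose and 54 fell, and with dCas12a-VPR 592 rose and 457 fell.

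**Figure D3:**
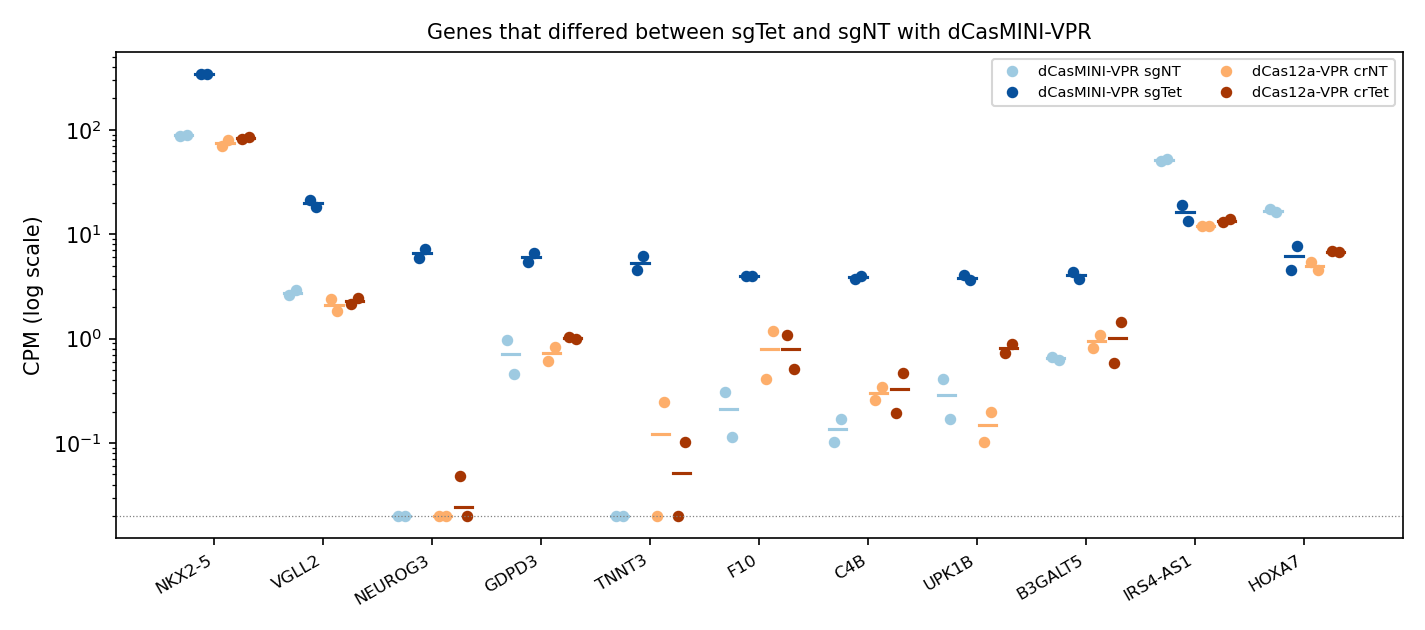
CPM (log axis) in each library of genes that rose or fell with the Tet guide and dCasMINI-VPR; libraries without reads sit on the dotted line. NKX2-5 lies at 343 CPM in sgTet against 88.2 CPM in sgNT and 83.0 CPM in crTet, and IRS4-AS1 at 51.5 CPM in sgNT against 16.2 CPM in sgTet and 13.5 CPM in crTet.

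Among the gene lists with dCasMINI-VPR, the mitochondrial mRNAs and the p53 targets had the smallest camera p. Of 26 measured p53 targets 7 fell and none rose (1 up and 14 down adjusted over the list alone; camera adjusted p = 1e-13, and adjusted p = 0.24 with an estimated correlation). TNFRSF10B, a death receptor gene, fell by 0.43 (adjusted p = 0.00149) and the DNA damage gene GADD45A fell by 0.49 (adjusted p = 0.00158), and both calls were lost without sgNT replicate 1 (adjusted p = 0.129 and 0.118). Of 13 mitochondrially encoded mRNAs, the complex I subunit MT-ND3 rose by 0.57 (adjusted p = 7.93e-05) and so did the cytochrome oxidase subunit MT-CO3 by 0.38 (adjusted p = 0.0022), with the latter call lost without sgNT replicate 1 (0.213) or sgTet replicate 1 (0.0541). Adjusted over the list alone 10 rose (camera adjusted p = 6.17e-20, and adjusted p = 0.24 with an estimated correlation). Of 41 interferon-response genes, the antiviral synthetase OAS3 (-0.34) and the RNA sensor regulator DHX58 (-0.85) fell and none rose (0 up and 9 down adjusted over the list alone; camera adjusted p = 1.42e-05, and adjusted p = 0.469 with an estimated correlation). The OAS3 call was lost without sgNT replicate 1 (adjusted p = 0.28) or replicate 2 (0.128), and that of DHX58 without sgNT replicate 1 (0.444), sgTet replicate 1 (0.157) or crNT replicate 1 (0.0551), or with the length and GC trend removed (0.0568). The heat shock list held 1 riser among 19, the mitochondrial co-chaperonin HSPE1, from 12.1 to 26.7 CPM (adjusted p = 2.45e-04; 7 up and 1 down adjusted over the list alone; camera adjusted p = 0.00256, and adjusted p = 0.364 with an estimated correlation). HSPE1 has processed pseudogenes, so its reads may be shared.

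Ribosomal protein genes shifted by a median of 0.098 with dCasMINI-VPR, and of 0.058 under library size scaling (camera adjusted p = 3.87e-10, and adjusted p = 0.521 with an estimated correlation), and the list call was lost without sgTet replicate 2 (median 0.043, adjusted p = 0.288). Of the 77 measured, RPS27, RPL38, RPS26 and RPL23 rose, and 11 rose adjusted over the list alone. All 4 calls were lost without sgNT replicate 2 (adjusted p = 0.0569, 0.193, 0.317 and 0.373), and those of RPL38, RPS26 and RPL23 without sgNT replicate 1 (0.122, 0.286 and 0.342). RPS26 and RPL23 also lost theirs without crNT replicate 1 (0.0739 and 0.1) or crNT replicate 2 (0.0718 and 0.0985). The 50 nuclear oxidative phosphorylation genes shifted by a median of 0.086, and of 0.046 under library size scaling. That list call was lost without sgTet replicate 2. Of its members UQCRQ, UQCR10 and ATP5MF rose (6 up adjusted over the list alone; camera adjusted p = 2.39e-04, and adjusted p = 0.611 with an estimated correlation). Each of these 3 genes lost its call without an sgNT library: UQCRQ without replicate 1 (0.0656), ATP5MF without replicate 2 (0.0987), and UQCR10 without replicate 1 (0.188), replicate 2 (0.302) or sgTet replicate 1 (0.377). The unfolded protein response, NF-kB, hypoxia and glycolysis, G2 and M phase and fibroblast lists also passed camera, with at most 1 called member each and adjusted p from 0.24 to 0.521 with an estimated correlation. Each of these 5 list calls was lost without some library. Those of the first 2 were lost as follows: unfolded protein response without sgNT replicate 1 (adjusted p = 0.143) or sgTet replicate 2 (0.0891), and NF-kB without sgTet replicate 2 (0.105). Those of the others were lost as follows: hypoxia and glycolysis without sgNT replicate 1 (0.475), sgTet replicate 1 (0.295) or sgTet replicate 2 (0.0612), G2 and M phase without sgTet replicate 1 (0.467), and fibroblast without sgNT replicate 2 (0.384), sgTet replicate 1 (0.243) or sgTet replicate 2 (0.0891). With the length and GC trend removed, the hypoxia and glycolysis and the fibroblast lists also lost their calls (0.237 and 0.189), and the former with a replicate block within construct (0.0543).

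With dCas12a-VPR, the comparison of crTet with crNT found immediate early genes among those that rose. FOS, a subunit of the AP-1 transcription factor, rose 3.66-fold, from 242 ± 43.2 to 886 ± 63.4 CPM (1.87 ± 0.16, adjusted p = 0.00106). Its partner JUN rose 2.25-fold (1.17 ± 0.08, adjusted p = 3.32e-11) and DUSP1, a phosphatase that acts on MAP kinases, rose 2.52-fold, from 148 ± 20.2 to 374 ± 21.2 CPM (1.33 ± 0.08, adjusted p = 6.19e-13). JUNB rose by 0.79 (adjusted p = 1.23e-05) and MYC by 0.57 (adjusted p = 6.82e-05). AMH, the anti-Müllerian hormone gene, rose from 3.45 to 10.6 CPM (adjusted p = 2.42e-05), and RASD1, a Ras-related gene, from 2.51 to 7.74 CPM (adjusted p = 2.05e-04). SNORD3A, a small nucleolar RNA that normally lacks a poly(A) tail, went from 0.752 to 6.30 CPM (adjusted p = 3.9e-05). The pseudogene ZNF767P fell by 1.07 (adjusted p = 1.98e-04). These 9 genes were called whichever library was left out. For AMH, DUSP1, JUN, FOS, MYC, RASD1 and SNORD3A the crNT mean was the lowest of the 4 groups, and for JUNB it was not.

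In all, 592 genes rose and 457 fell with dCas12a-VPR, by a median of 1.34-fold, and 52 of the risers by at least 2-fold. The count of 1049 became 135 without crNT replicate 1, 342 without crNT replicate 2, 518 without crTet replicate 1 and 449 without crTet replicate 2, and 1963 and 1965 without sgTet replicate 1 and replicate 2. Scaling by library size alone gave 432 higher and 600 lower. Removing the length and GC trend gave 641 and 671, with 830 of the 1049 among them.

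Of 32 immediate early genes 11 rose with dCas12a-VPR (14 up and 2 down adjusted over the list alone; camera adjusted p = 4.29e-12, and adjusted p = 0.127 with an estimated correlation). The members that fell were ATF3 (-0.42, adjusted p = 7.89e-04), lost without crNT replicate 1 (0.0535), and FOSL2 (-0.61, adjusted p = 0.048), chosen after its values were seen. The FOSL2 call was lost without either sgNT library (0.0551 and 0.0529), either crNT library (0.395 and 0.173) or either crTet library (0.157 and 0.205). Interferon-response genes fell, 22 of 41, with a median of -0.39 (2 up and 25 down adjusted over the list alone; camera adjusted p = 2e-18, and adjusted p = 0.127 with an estimated correlation). The deubiquitinase USP18 fell by 0.57 (adjusted p = 2.45e-05), and the antiviral genes DDX60 by 0.65 and HERC5 by 0.54 (adjusted p = 9.15e-05 for both). IFITM1 (0.42, adjusted p = 0.0164) and RIGI (1.48, adjusted p = 0.0311), chosen after their values were seen, were the members that rose. Both calls were lost without either crNT library (IFITM1 0.116 and 0.183, RIGI 0.285 and 0.135) or either crTet library (IFITM1 0.0522 and 0.141, RIGI 0.148 and 0.0914), and that of IFITM1 with the length and GC trend removed (0.159). The crNT libraries, against which these changes were measured, also had the largest unmapped share, 14.4% and 12.7%, against 9.55% and 9.37% in crTet.

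Of 26 p53 targets 12 fell with dCas12a-VPR (17 adjusted over the list alone; camera adjusted p = 7.91e-17, and adjusted p = 0.127 with an estimated correlation). CDKN1A, the cell cycle inhibitor p21, fell by 0.49, from 382 to 272 CPM (adjusted p = 7.76e-05), SESN2 by 0.52 (adjusted p = 4.47e-05) and the ribonucleotide reductase subunit RRM2B by 0.53 (adjusted p = 9.15e-05). Of 21 unfolded protein response genes 8 fell (10 adjusted over the list alone; camera adjusted p = 1.26e-06, and adjusted p = 0.127 with an estimated correlation), among them its transcription factor XBP1, by 0.53 (adjusted p = 2.45e-05). Of 25 ATF4 response genes 8 fell and 1 rose (2 up and 10 down adjusted over the list alone; camera adjusted p = 9.27e-06, and adjusted p = 0.186 with an estimated correlation). The riser, CEBPB (0.41, adjusted p = 0.0274), was chosen after its values were seen and lost its call without either crNT library (0.235 and 0.211) or either crTet library (0.0792 and 0.168), or with the length and GC trend removed (0.242). Of 30 hypoxia and glycolysis genes 9 fell (3 up and 14 down adjusted over the list alone; camera adjusted p = 5.57e-05, and adjusted p = 0.186 with an estimated correlation), among them the collagen hydroxylase subunit P4HA1 (-0.52, adjusted p = 2.78e-04) and the glucose transporter SLC2A3 (-0.77, adjusted p = 6.22e-04).

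Genes of the ribosome and the respiratory chain rose with dCas12a-VPR and none of them fell. Of 77 ribosomal protein genes 20 rose (32 adjusted over the list alone; camera adjusted p = 4.04e-20, and adjusted p = 0.3 with an estimated correlation), with FAU at 0.59 (adjusted p = 9.24e-05) and RPL38 at 0.51 (adjusted p = 2.78e-04). Of 13 mitochondrially encoded mRNAs 8 rose (13 adjusted over the list alone; camera adjusted p = 3.05e-20, and adjusted p = 0.141 with an estimated correlation), with MT-ND3 at 0.55 (adjusted p = 9.05e-05). Of 50 nuclear oxidative phosphorylation genes 13 rose (19 adjusted over the list alone; camera adjusted p = 1.34e-09, and adjusted p = 0.329 with an estimated correlation), with UQCRQ, a complex III subunit, going from 26.7 to 46.8 CPM (adjusted p = 7.1e-05). HSPE1 rose from 6.78 to 15.9 CPM (adjusted p = 1.62e-04), the single riser among 19 heat shock genes (2 adjusted over the list alone; camera adjusted p = 0.0165, and adjusted p = 0.3 with an estimated correlation), a list call lost without crTet replicate 2 (adjusted p = 0.117). The proliferation marker MKI67 rose from 25.1 to 58.8 CPM (adjusted p = 0.00484) and the mitotic kinesin CENPE from 6.84 to 14.7 CPM (adjusted p = 0.00135). They and the ubiquitin-conjugating enzyme UBE2C (0.37), whose call was lost without crNT replicate 1 (0.285) or crTet replicate 2 (0.124), were the called members among 29 G2 and M phase genes (3 adjusted over the list alone). That list had a median of 0.016, of -0.014 under library size scaling and of 0.074 with the length and GC trend removed. It did not pass camera (adjusted p = 0.0768, and adjusted p = 0.695 with an estimated correlation), but passed with the length and GC trend removed (5.22e-04).

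**Figure D4:**
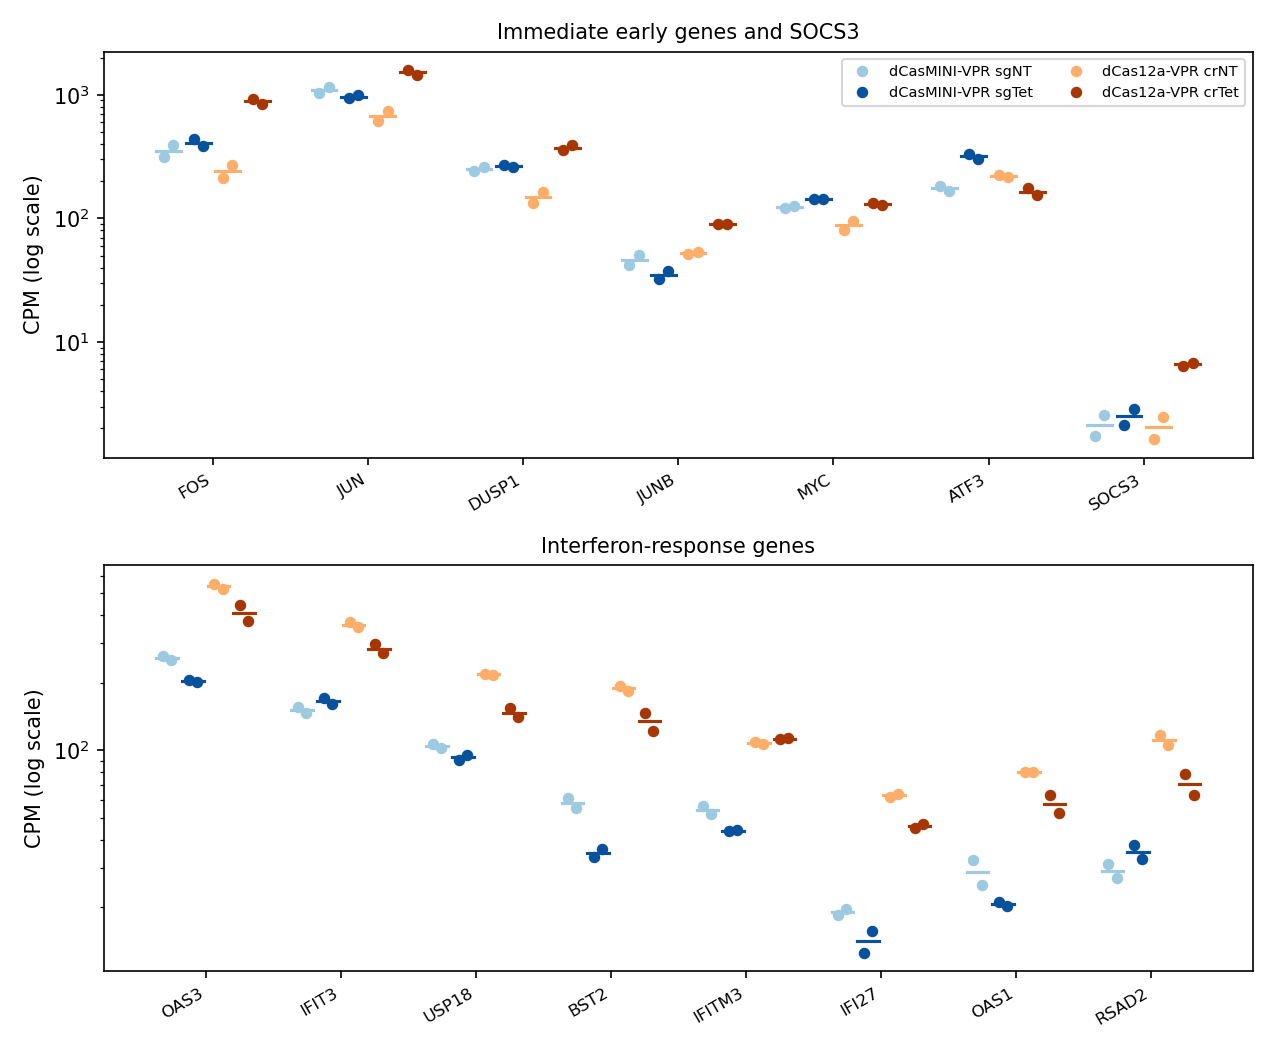
CPM (log axis) in each library of immediate early genes and SOCS3 in the upper panel and interferon-response genes in the lower panel, with points as libraries of the 4 groups. FOS lies at 886 CPM in crTet against 242 CPM in crNT, and OAS3 at 539 and 410 CPM in crNT and crTet against 259 and 204 CPM in sgNT and sgTet.

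Whether the guide effect differed between the activators, each with guides of its own, was tested as (sgTet minus sgNT) minus (crTet minus crNT). NKX2-5 (1.80 ± 0.11, adjusted p = 8.52e-13) and VGLL2 (2.72 ± 0.36, adjusted p = 2.04e-05) rose more with dCasMINI-VPR, with 74.5 and 83.0 CPM for NKX2-5 and 2.12 and 2.29 CPM for VGLL2 in crNT and crTet. JUN (-1.35 ± 0.11, adjusted p = 4.12e-09), DUSP1 (-1.25 ± 0.11, adjusted p = 1.24e-08) and JUNB (-1.18 ± 0.15, adjusted p = 8.41e-06) rose more with dCas12a-VPR. ATF3 went the other way (1.28 ± 0.11, adjusted p = 3.12e-09), up in sgTet and down in crTet. IRS4-AS1 (-1.84 ± 0.20, adjusted p = 7e-07), HOXA7 (-1.90 ± 0.30, adjusted p = 5.55e-04) and AMH (-1.69 ± 0.29, adjusted p = 0.00157) had lower guide effects with dCasMINI-VPR, and the antiviral gene RSAD2 a higher one (0.93 ± 0.15, adjusted p = 0.0013). These 10 genes were called whichever library was left out. GDPD3 (2.59 ± 0.63, adjusted p = 0.03) was not, with adjusted p of 0.222 without sgNT replicate 2, 0.0941 and 0.189 without crNT replicate 1 and 2, and 0.0708 and 0.0653 without crTet replicate 1 and 2. The test gave no usable estimate for NEUROG3, which had no read in sgNT or crNT and 0.0244 CPM in crTet.

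Of the 32 immediate early genes 8 had a guide effect lower with dCasMINI-VPR and ATF3 a higher one (1 up and 15 down adjusted over the list alone; median -0.52; camera adjusted p = 2.04e-12, and adjusted p = 0.382 with an estimated correlation). With the length and GC trend removed, the median was -0.31 (camera adjusted p = 1.29e-09). In total 84 genes had a higher and 140 a lower guide effect with dCasMINI-VPR, and DESeq2 gave 143 and 156. Removing the length and GC trend gave 96 and 102, and only 110 of the 224 were among them. The count of 224 became 28 without sgNT replicate 2, 30 and 71 without crNT replicate 1 and 2, 111 without crTet replicate 1, and 1835 without sgTet replicate 2.

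The guide effects of the 2 activators were only weakly related across all genes. Across 16605 genes other than EGFP their log2 fold changes had a Pearson r of 0.09 and a Spearman rho of 0.06, and 50.2% had the same sign, where genes are not independent replicates. The fold changes followed GC content in opposite directions, with a Spearman rho across genes of -0.399 with dCasMINI-VPR and 0.317 with dCas12a-VPR. With the length and GC trend removed, the Spearman rho between the guide effects was 0.147, and 55.8% of the genes had the same sign. Among called genes, 24 of the 77 higher with dCasMINI-VPR were also among the 591 higher with dCas12a-VPR, against 2.74 for independent lists (one-sided Fisher's exact p = 1.01e-16). Likewise 15 of 54 were among the 457 lower, against 1.49 (one-sided Fisher's exact p = 1.01e-11). Another 3 genes were called in opposite directions. These tests of overlap treat genes as independent, which they are not, so their p-values overstate the evidence. The 2 contrasts share no library. The correlation of log2(CPM + 1) between targeting and non-targeting means of 2 libraries was 0.995 with dCasMINI-VPR and 0.994 with dCas12a-VPR. Single replicate libraries gave 0.994 in sgNT, 0.993 in sgTet, 0.996 in crNT and 0.994 in crTet. Means carry less noise than single libraries, so these values are not like for like and do not weigh guide effects against replicate spread.

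The mean guide effect over both activators was tested in the same model, since both guides are named Tet. KISS1R, the kisspeptin receptor gene, rose (2.26 ± 0.34, adjusted p = 5.71e-05), from 0.608 to 3.96 CPM with dCasMINI-VPR and from 0.659 to 2.30 CPM with dCas12a-VPR, and LIMS2 rose by 1.32 (adjusted p = 1.28e-04). The ribosomal protein genes RPS27 (0.46 ± 0.05, adjusted p = 1.54e-06) and RPL38 (0.46 ± 0.06, adjusted p = 1.09e-05) and the mitochondrial MT-ND3 (0.56 ± 0.06, adjusted p = 2.87e-07) rose. So did UQCRQ (0.73 ± 0.08, adjusted p = 9.77e-07), the ATP synthase subunit ATP5MF (0.85 ± 0.10, adjusted p = 1.6e-06) and HSPE1 (1.19, adjusted p = 9.77e-07). TNFRSF10B (-0.46 ± 0.05, adjusted p = 1.22e-06), CDKN1A (-0.41 ± 0.05, adjusted p = 3.71e-06) and GADD45A (-0.48 ± 0.06, adjusted p = 6.6e-06) fell, as did OAS3 (-0.37, adjusted p = 2.59e-05) and XBP1 (-0.36, adjusted p = 2.64e-05). All of these were called whichever library was left out.

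By list, the mean guide effect raised 24 of 77 ribosomal protein genes (36 adjusted over the list alone; camera adjusted p = 2.13e-25, and adjusted p = 0.231 with an estimated correlation). It raised 9 of 13 mitochondrial mRNAs (13 adjusted over the list alone; camera adjusted p = 7.45e-30, and adjusted p = 0.116 with an estimated correlation). Among 50 nuclear oxidative phosphorylation genes 14 rose (24 adjusted over the list alone; camera adjusted p = 2.52e-11, and adjusted p = 0.298 with an estimated correlation). None of these 3 lists had a member that fell. It lowered 15 of 26 p53 targets (22 adjusted over the list alone; camera adjusted p = 8.01e-25, and adjusted p = 0.103 with an estimated correlation). Also lower were 18 of 41 interferon-response genes (1 up and 24 down adjusted over the list alone; camera adjusted p = 1.74e-18, and adjusted p = 0.116 with an estimated correlation). The unfolded protein response had 7 of 21 genes lower (8 adjusted over the list alone; camera adjusted p = 4.38e-08, and adjusted p = 0.116 with an estimated correlation). In total 397 genes rose and 286 fell, with 252 and 450 under library size scaling, and 663 and 550 with the length and GC trend removed, 649 of the 683 among them. The count of 683 became 267 and 411 without sgNT replicate 1 and 2, 207 and 375 without crNT replicate 1 and 2, and 1499 without sgTet replicate 2.

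Among the lists for the difference between dCasMINI-VPR and dCas12a-VPR, the interferon response had the smallest camera p. BST2 lay at 58.3 and 34.9 CPM in sgNT and sgTet and at 189 and 135 CPM in crNT and crTet (-1.82 ± 0.07 for dCasMINI-VPR minus dCas12a-VPR, adjusted p = 1.33e-19). The interferon-induced genes IFI27 (-1.71 ± 0.08, adjusted p = 1.48e-16), MX2 (-1.70 ± 0.16, adjusted p = 2.62e-09), OAS2 (-1.64 ± 0.08, adjusted p = 1.13e-15), OAS3 (-1.03 ± 0.05, adjusted p = 2.66e-16) and IFIT3 (-1.02, adjusted p = 3.7e-16) were also lower with dCasMINI-VPR. Of 41 interferon-response genes 37 were lower and none higher, with a median of -1.02 (1 up and 39 down adjusted over the list alone; camera adjusted p = 4.23e-80, and adjusted p = 0.0164 with an estimated correlation). The list was lower with the targeting guides alone (camera adjusted p = 5.06e-65) and with the non-targeting guides alone (camera adjusted p = 1.06e-70). HES1, a Notch target, was higher with dCasMINI-VPR (1.01 ± 0.08, adjusted p = 5.2e-11), with 59.1 and 76.9 CPM in sgNT and sgTet and 23.8 and 47.1 CPM in crNT and crTet. SLC15A3, a lysosomal peptide transporter, was lower (-2.16 ± 0.28, adjusted p = 1.68e-06). All of these genes were called whichever library was left out, but SLC15A3 lost its call with reverse-strand counts (adjusted p = 0.0624).

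Immediate early genes were lower with dCasMINI-VPR over both guides in 14 of 32 cases and higher in 3, ATF3, MYC and DUSP5 (5 up and 14 down adjusted over the list alone; camera adjusted p = 1.86e-06, and adjusted p = 0.142 with an estimated correlation). IER2 (-0.86 ± 0.06, adjusted p = 1.08e-12) and JUNB (-0.77, adjusted p = 1.78e-09) led the lower ones, while DUSP5 (0.37), which like MYC was chosen after its values were seen, lost its call without crNT replicate 2 (adjusted p = 0.0672). By guide, the immediate early list was lower with dCasMINI-VPR at the targeting guides alone (camera adjusted p = 2.35e-16, median crTet minus sgTet 0.56). At the non-targeting guides alone it did not pass (camera adjusted p = 0.923, median crNT minus sgNT 0.042). Of the p53 targets 8 of 26 were lower, with CDKN1A at -0.68 ± 0.05 (adjusted p = 6.96e-12). Adjusted over that list alone 1 was up and 12 down (camera adjusted p = 2.66e-06, and adjusted p = 0.142 with an estimated correlation). Of 25 ATF4 response genes 12 were lower and ATF3 higher (1 up and 14 down adjusted over the list alone; camera adjusted p = 6.24e-08, and adjusted p = 0.113 with an estimated correlation). In total 802 genes were higher and 863 lower with dCasMINI-VPR, by a median of 1.26-fold. Library size scaling gave 625 and 969, and removing the length and GC trend gave 1370 and 1088, so the balance depends on the scaling. The count of 1665 became 839 without sgNT replicate 2, 865 and 926 without crNT replicate 1 and 2, and 711 with the targeting libraries alone. The non-targeting libraries alone gave 1276. The names of the deposited files carry one prefix for the 4 dCasMINI-VPR libraries and another for the 4 dCas12a-VPR libraries. The labels do not say whether the prefixes mark separate preparations. If they do, preparation and construct cannot be told apart. Each construct also came with guides of its own (sgNT and sgTet, or crNT and crTet), so construct and guide RNA cannot be told apart either.

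**Figure D5:**
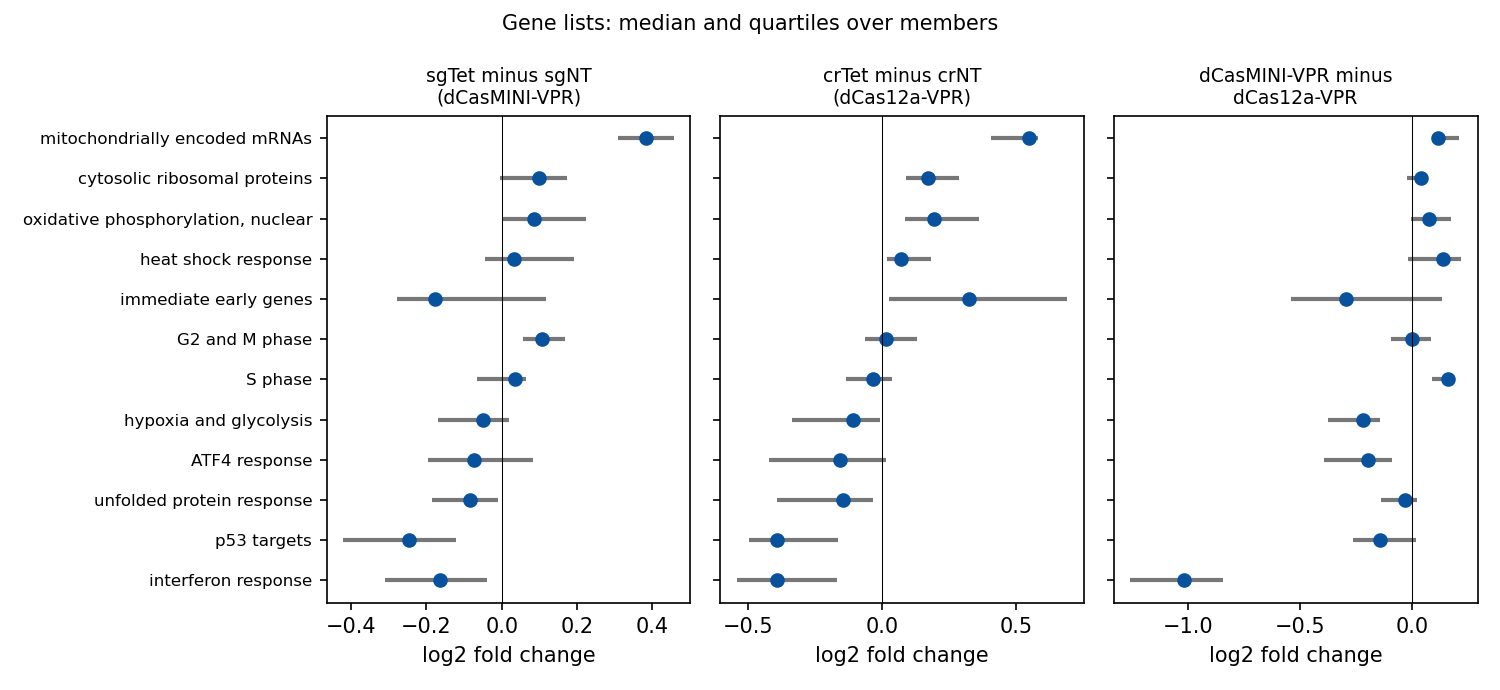
Median (point) and quartiles (line) of the log2 fold changes of 12 gene lists for the guide effect with dCasMINI-VPR, the guide effect with dCas12a-VPR and the difference between constructs. The interferon-response list has medians of -0.16, -0.39 and -1.02 in these 3 contrasts.

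Markers of other cell types and several further lists did not pass camera for the mean guide effect. The adjusted p was 0.981 for replication-dependent histones, 0.563 for S phase, 0.0566 for cholesterol synthesis, 0.701 for metallothioneins, 0.288 for the benchmark genes of activation studies, 0.981 for neuronal, 0.373 for haematopoietic, 0.563 for fibroblast, 0.981 for endothelial and 0.701 for epithelial markers. Single markers were called higher: the keratins KRT18 (0.26, adjusted p = 0.0288) and KRT19 (adjusted p = 0.0475) and the neurofilament gene NEFM (0.35, adjusted p = 0.0496). KRT19 had 0 CPM in sgNT, 0.470 in sgTet, 0.102 in crNT and 0.346 in crTet. The KRT18 call was lost without sgNT replicate 1 or 2 (0.0665 and 0.15), crNT replicate 1 (0.294) or crTet replicate 2 (0.138). That of NEFM was lost without sgNT replicate 1 (0.339), sgTet replicate 1 (0.0523), crNT replicate 1 or 2 (0.16 and 0.18) or crTet replicate 1 (0.215). That of KRT19 was lost without sgNT replicate 1 or 2 (0.228 and 0.167), sgTet replicate 1 (0.143), crNT replicate 1 or 2 (0.071 and 0.189) or crTet replicate 1 or 2 (0.264 and 0.069). Under library size scaling all 3 calls were lost (KRT18 0.0677, KRT19 0.0538, NEFM 0.093). For the histone and endothelial lists the median and the mean fold change differed in sign, and for the neuronal list both were negative while camera pointed up. NF-kB targets, a list of interest since VPR holds a p65 domain, were lower by camera (adjusted p = 0.0147, and adjusted p = 0.174 with an estimated correlation; 0 up and 4 down adjusted over the list alone). RELB fell (-0.71, adjusted p = 0.0104), a call lost without sgNT replicate 1 (0.282) or crNT replicate 1 (0.0652). The apoptosis inhibitor BIRC2 fell (-0.24, adjusted p = 0.0405), a call lost without sgNT replicate 1 and 2 (0.198 and 0.0864), crNT replicate 1 and 2 (0.206 and 0.132) or crTet replicate 2 (0.157).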

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

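The tests of a response to reporter activation, of the unmapped share, of the length and GC trend within each guide effect, of the lists without each library and of other splits for the mean guide effect were chosen only after the result was seen.

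The results listed here were taken up because the guide effect differed between dCasMINI-VPR and dCas12a-VPR, by the test of that difference in edgeR for 224 genes and by camera in limma for 5 gene lists. Values are the log2 guide effect with dCasMINI-VPR minus that with dCas12a-VPR. The genes called whichever library was left out were VGLL2 at 2.72, NKX2-5 at 1.80, ATF3 at 1.28, RSAD2 at 0.93, HOXA7 at -1.90, IRS4-AS1 at -1.84, AMH at -1.69, JUN at -1.35, DUSP1 at -1.25 and JUNB at -1.18. The genes that lost their call without at least 1 library were GDPD3 at 2.59, RMDN2 at 1.88, BAALC-AS1 at 1.60 and USH1G at 1.501. Others were DDX60 at 0.62, SEC24D at 0.58, IFIT3 at 0.49, HERC5 at 0.47 and CDC6 at 0.39. On the other side these were SNORD3A at -2.38, LBHD1 at -2.10, GTF2IP13 at -1.68, KLF4 at -0.92, CEBPB at -0.73, RPL30 at -0.66, SDF2L1 at -0.51 and UHRF1 at -0.51. Chosen after their values were seen, C4B stood at 4.66, F10 at 4.17 and B3GALT5 at 2.55, and for TNNT3 the rise in CPM was larger by 5.39 with dCasMINI-VPR; these 4 also lost their call without at least 1 library. With the length and GC trend removed only 110 of the 224 genes were called, and RMDN2 (adjusted p = 0.0802), BAALC-AS1 (0.0519), DDX60 (0.0581), SDF2L1 (0.581), CEBPB (0.183) and RPL30 (0.258) were not. The 5 lists had medians of 0.14 (interferon response), -0.52 (immediate early genes), 0.17 (ATF4 response), -0.090 (ribosomal proteins) and -0.10 (nuclear oxidative phosphorylation). Except for immediate early genes, each list lost its call without at least 1 library: interferon response without sgTet replicate 2 (adjusted p = 0.0906) or crTet replicate 2 (0.0903), and ATF4 response without sgNT replicate 2 (0.115) or sgTet replicate 2 (0.147). So did ribosomal proteins without sgTet replicate 1 (0.545), crNT replicate 1 (0.142) or crTet replicate 2 (0.672), and oxidative phosphorylation without sgNT replicate 1 (0.172), sgTet replicate 1 (0.545), crNT replicate 1 (0.17) or crTet replicate 2 (0.776). The median of interferon response was 0.23 without crNT replicate 2, 0.30 without crTet replicate 1 and 0.069 without crTet replicate 2, and that of ATF4 response was 0.10 without sgTet replicate 2. That of ribosomal proteins was -0.024 and -0.14 without sgTet replicate 1 and 2, -0.052 and -0.14 without crNT replicate 1 and 2, and -0.17 and 0.0079 without crTet replicate 1 and 2. That of oxidative phosphorylation was -0.033 and -0.18 without sgTet replicate 1 and 2, -0.17 without crNT replicate 2, and -0.24 and -0.0080 without crTet replicate 1 and 2. With the length and GC trend removed, the immediate early genes had a median of -0.31 (camera adjusted p = 1.29e-09), and oxidative phosphorylation had one of -0.060 and lost its call (0.0887). With an estimated correlation no list passed for this difference.

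The first pattern weighed is the set of 29 genes that were at least 4-fold higher with the Tet guide and dCasMINI-VPR, most of them near silent before. EGFP rose with dCas12a-VPR by 0.751 of its rise in CPM with dCasMINI-VPR, while the median of that ratio over the 29 genes was 0.00792. For the set as a whole this argues against a response to reporter activation. The 95% interval of 0 to 0.0190 came from 10000 resamples of genes, not of libraries. The genes were chosen for their rise with dCasMINI-VPR, which can lower the ratio, and 8 were called in the difference between guide effects. Of the 3 called with dCas12a-VPR, KISS1R and UPK1B rose (ratios 0.490 and 0.185) and LINC02798 fell. Cells of another type remain open. Of 45 measured markers of 5 cell types 0% were called higher at 2-fold or more, but the upper limit is 7.87%. Adjusted over the list alone, 3 of 9 epithelial markers rose and 1 fell. The sort on mCherry and BFP would keep transfected cells of any kind. Activation at separate genomic sites, which could reflect guide binding outside the reporter, also remains open: 3 pairs of the genes started within 200 kb (permutation p = 0.0004 over 10000 random sets), but 2 of these pairs overlap and the other is C4A and C4B, which leaves 1 pair of genes that do not overlap (permutation p = 0.0933).

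The second pattern weighed is the rise of ribosomal protein and respiratory chain genes with the Tet guides, where with an estimated correlation none of the 3 lists passed with dCasMINI-VPR (adjusted p = 0.521, 0.24 and 0.611 for ribosomal, mitochondrial and oxidative phosphorylation), dCas12a-VPR (0.3, 0.141 and 0.329) or in the mean (0.231, 0.116 and 0.298). The mean guide effect cannot test a trend of the libraries on transcript length and GC content, since the GC trends were opposite and cancelled (Spearman rho of -0.399 with dCasMINI-VPR, 0.317 with dCas12a-VPR and -0.0030 in the mean), and the median of the ribosomal protein list was 0.123 before and 0.124 after its removal. Within each guide effect the tables argue against that trend as the whole source: with it removed, the ribosomal protein, mitochondrial and nuclear oxidative phosphorylation lists kept at least 75.5% of their medians (0.098 to 0.079 and 0.172 to 0.148 for ribosomal proteins), with camera adjusted p of at most 4.64e-04. They also argue against a single outlying library as the whole source for the 3 lists with dCas12a-VPR (adjusted p of at most 0.0178 without each library), the mitochondrial list with dCasMINI-VPR (8.07e-15) and the ribosomal protein list in the mean (6.49e-14), but the size depended on 1 library: the mitochondrial median with dCasMINI-VPR fell from 0.38 to 0.15 without sgTet replicate 1, and without crTet replicate 2 the ribosomal protein median fell from 0.17 to 0.10 with dCas12a-VPR and from 0.123 to 0.078 in the mean, and that of oxidative phosphorylation with dCas12a-VPR from 0.19 to 0.13 (0.31 without crTet replicate 1). With dCasMINI-VPR the rise of ribosomal protein and oxidative phosphorylation genes may rest on sgTet replicate 2, since without it the list calls were lost (0.288 and 0.95) and the medians fell from 0.098 to 0.043 and from 0.086 to 0.018 (the latter 0.16 without sgTet replicate 1), and a biological response to reporter activation and a difference in handling between targeting and non-targeting cells were not tested and remain open.

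The third pattern weighed is the interferon response, in 2 parts. Between crNT and crTet, the lowest crNT library had an unmapped share 3.11 percentage points above the highest crTet library. What lies behind the unmapped reads, such as plasmid RNA or a difference in RNA or library quality, may contribute there. The unmapped reads were not examined, so these cannot be told apart. Between dCas12a-VPR and dCasMINI-VPR at the targeting guide, the tables argue against the unmapped share, since its gap of 0.718 points between crTet and sgTet was 17.5% of the gap of 4.09 points between crNT and crTet, while the list differed by 0.92 against 0.40 in median log2. They also argue against a single library, since the highest camera adjusted p of the list for the construct difference was 4.58e-82 with each library left out. If the file prefixes, one per construct, mark separate preparations, these and the construct cannot be told apart. Each construct also came with guides of its own, so guide RNA and construct cannot be told apart either. A biological difference between the constructs stays open as untested.

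For the mean guide effect with construct as a term, 1 of 34 splits of the 8 libraries, the real one, gave as many called genes (245, against at most 51 in any other). For the construct difference with guide as a term, 1 of 34 splits, again the real one, gave as many (901, against at most 7). All other splits but 1 part the libraries of some group, among them the split that gave 51. The 1 other split that keeps each group whole gave 11 genes with construct as a term and 7 with guide as a term.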

How the results depend on the processing

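The correction for length and GC content and the list tests without each library were chosen only after the result was seen.

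Counts of called genes stayed within 1.5 times their reported values for all 5 contrasts with DESeq2, RLE factors, library size alone, the stricter filter, reverse-strand counts and without mitochondrial genes. The genes behind similar counts could differ. Reverse-strand counts with dCasMINI-VPR gave 99 genes, of which 66 were among the 132 reported. DESeq2 gave 299 for the difference, of which 167 were among the 224 reported, and gave no adjusted p for 10302 of 16606 genes. With glmTreat against 1.5-fold, which asks for larger changes, the counts were 26 and 5 for the guide effects with dCasMINI-VPR and dCas12a-VPR, 10 for their difference, 7 for their mean and 65 for the construct difference. Without a filter, dCasMINI-VPR gave 276 genes and the difference 450. Forward-strand counts, with about 0.5 of the reads, gave 661 with dCas12a-VPR and 106 for the difference. Removing the length and GC trend gave 216 with dCasMINI-VPR and 1213 for the mean, and fits of only 1 construct's 4 libraries, which estimate the spread anew, gave 84 and 1785. A replicate block over all groups gave 400 for the difference, and a block within construct gave 347 for it. For the construct difference the block within construct gave 559. There it compared the replicate 1 levels of the constructs alone, so that count is not like for like. For the construct difference the targeting libraries alone gave 711 and the non-targeting libraries alone gave 1276, each with fewer libraries. The lower count of the targeting libraries is therefore not due to their number. Leaving out each library gave 50 to 1475 (dCasMINI-VPR), 135 to 1965 (dCas12a-VPR), 28 to 1835 (difference), 207 to 1499 (mean) and 839 to 2403 (construct). The lowest counts came without an sgNT or crNT library, and the highest without sgTet replicate 2, while without sgTet replicate 1 dCasMINI-VPR gave 88. The sgTet libraries are not in the dCas12a-VPR contrast. Leaving one out can change that count only through what the model shares, which is the spread, the filter and the scaling. The cause of the other changes was not tested. Reversed signs were seen for UQCR10 with dCasMINI-VPR (-0.051, forward strand), LBHD1 with dCas12a-VPR (-0.027, forward strand) and SLC25A25-AS1 with dCas12a-VPR (-0.058, reverse strand), and the cause was not tested. The ribosomal protein list ran from an adjusted p of 1.36e-13 to 0.672 for the difference, where it turned upward without crTet replicate 2 (0.672), and from 6.58e-09 to 0.678 for the construct difference, where it turned downward without sgTet replicate 2 (0.678) or crTet replicate 1 (0.405). The oxidative phosphorylation list ran from 2.51e-07 to 0.776 for the difference and turned upward without crTet replicate 2. Of the named genes called, 19 of 48 with dCasMINI-VPR, 32 of 76 with dCas12a-VPR, 10 of 31 for the difference, 39 of 65 for the mean and 53 of 92 for the construct difference were called in all 8 fits with a library left out. Of 52 list calls, 3 passed with an estimated correlation (interferon response, hypoxia and glycolysis, and S phase for the construct difference), 24 with fry and 50 with a replicate block within construct. For list calls of the construct difference that block too compared replicate 1 levels alone. The correlation of targeting with non-targeting means was 0.989 and 0.990 (dCasMINI-VPR and dCas12a-VPR) with a pseudocount of 0.1. Those of single replicate libraries, which are not like for like, fell to between 0.985 and 0.988. Over all genes with a read the correlation of means was 0.997 in both, with the cause not tested. The correlation of the guide effects was 0.107 (Spearman rho 0.147) with the trend removed, and it was not recomputed under a block. With 2 libraries per group and 3 reads as the floor, genes below about 0.142 CPM were not measurable in a library.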

Other observations

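Among the tests given here, those of sgNT against crNT for single genes were chosen only after the result was seen.

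Beyond the interferon response, the 2 activators' cells differed in metabolic, replication and chaperone genes. Of 30 hypoxia and glycolysis genes 19 were lower with dCasMINI-VPR and none higher (1 up and 23 down adjusted over the list alone; camera adjusted p = 6.46e-17, and adjusted p = 0.0414 with an estimated correlation). Among them were the enolase ENO2 (-0.62 ± 0.07, adjusted p = 5.38e-08), the glucose transporter SLC2A3 (-0.78 ± 0.10, adjusted p = 1.29e-06) and P4HA1 (-0.49, adjusted p = 9.2e-07). Of 30 S phase genes 14 were higher and none lower (18 adjusted over the list alone; camera adjusted p = 6.5e-11, and adjusted p = 0.0164 with an estimated correlation). Among them were the checkpoint adaptor CLSPN (0.40, adjusted p = 7.31e-05), UHRF1, which maintains DNA methylation (0.33, adjusted p = 3.02e-05), and cyclin E gene CCNE1 (0.47, adjusted p = 9.79e-05). Both lists passed within the targeting guides (camera adjusted p = 1.09e-09 and 3.28e-10) and within the non-targeting guides (2.8e-13 and 4.52e-05). Of 19 heat shock genes 8 were higher, such as HSPH1 (0.31, adjusted p = 3.61e-05), and 3 were lower (10 up and 3 down adjusted over the list alone; camera adjusted p = 4.61e-04, and adjusted p = 0.142 with an estimated correlation). The lower ones, DNAJB1 (-0.25), DNAJB4 (-0.29) and HSPB1 (-0.19), were chosen after their values were seen. DNAJB4 lost its call without sgNT replicate 1 and 2 (0.0655 and 0.0635), crNT replicate 1 (0.129) or crTet replicate 2 (0.0529). HSPB1 lost its call without sgNT replicate 1 and 2 (0.111 and 0.0536), crNT replicate 1 and 2 (0.0732 and 0.109) or crTet replicate 2 (0.0761). The keratin KRT8, which HEK293T cells are known to express, was lower with dCasMINI-VPR (-0.71 ± 0.06, adjusted p = 3.84e-10), as were the fibroblast markers COL6A2 (-0.36, adjusted p = 4.43e-04) and FN1 (-0.35, adjusted p = 0.00153). With a replicate block within construct, which compared the replicate 1 levels of the constructs alone, DNAJB1 and FN1 were not called (adjusted p = 0.152 and 0.0561). FN1 also lost its call with forward-strand counts (0.11).

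Marker lists also differed between the activators. Of 12 fibroblast markers 5 were lower with dCasMINI-VPR and none higher (5 down adjusted over the list alone; median -0.31; camera adjusted p = 4.3e-04, and adjusted p = 0.142 with an estimated correlation). Of 9 epithelial markers 2 were lower and none higher (2 down adjusted over the list alone; median -0.70; camera adjusted p = 0.00256, and adjusted p = 0.113 with an estimated correlation). The epithelial median was -0.34 without crNT replicate 1 and -0.43 without crTet replicate 1. With the targeting guides alone the fibroblast list passed and the epithelial list did not (camera adjusted p = 3.94e-05 and 0.0676). With the non-targeting guides alone the epithelial list passed and the fibroblast list did not (0.00481 and 0.147). Both lists were lower with dCasMINI-VPR at either guide, and neither passed for the difference between the guide effects (camera adjusted p = 0.0825 for fibroblast and 0.493 for epithelial).

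Some guide effects came with a level that stood apart in a non-targeting group. IRS4-AS1 lay at 51.5 ± 1.61 CPM in sgNT and at 16.2 and 13.5 CPM in sgTet and crTet, and sgNT minus crNT was 2.10 ± 0.14 (adjusted p = 8.27e-13). HOXA7 lay at 16.8 CPM in sgNT and at 6.12, 5.01 and 6.80 CPM in the other groups, and sgNT minus crNT was 1.75 ± 0.21 (adjusted p = 3.72e-07). AMH lay at 3.45 CPM in crNT and at 11.3, 10.7 and 10.6 CPM in sgNT, sgTet and crTet, and MKI67 at 25.1 CPM in crNT and at 58.3, 64.0 and 58.8 CPM. Of the 29 genes at least 4-fold higher with dCasMINI-VPR, 3 were called with dCas12a-VPR, and each of these calls was lost when 1 library was left out. UPK1B rose (2.37, adjusted p = 0.0326), lost without crNT replicate 1 and 2 (0.346 and 0.111) or crTet replicate 1 and 2 (0.0694 and 0.141). KISS1R rose (1.80, adjusted p = 0.0201), lost without crNT replicate 2 (0.282) or crTet replicate 1 and 2 (0.0937 and 0.0605). LINC02798, a long noncoding RNA chosen after its values were seen, fell (-3.17, adjusted p = 0.0318), lost without crNT replicate 1 and 2 (0.165 and 0.106) or crTet replicate 1 and 2 (0.141 and 0.145). C4A and the cytokine gene IL18 were called with dCasMINI-VPR but not without sgNT replicate 1 (adjusted p = 0.374 and 0.211) or sgNT replicate 2 (0.373 and 0.0974), and IL18 not without sgTet replicate 1 (0.133).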
